A study of Homo sapiens with 8 samples.

How the data were processed

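Polyadenylated RNA of 8 libraries of the human embryonic stem cell line SA001 was measured by targeted sequencing. Per the labels' protocols, libraries were made from 50 ng of RNA with an Ion AmpliSeq kit for the human transcriptome, which amplifies a short target per gene. The submitters' processing notes name TopHat2 2.0.8, Bowtie2 2.1.0, Partek and the build hg19, without saying how each was used. The gene annotation, the handling of reads that match several genes and the use of strand are not given in the sources used here.

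The authors deposited 1 table with a row for each of 27103 genes and a column for each library, in RPM, reads scaled to a common total per library. Where a gene had no reads the deposited RPM table lists a lowest value of 0.0001, which 7913 genes had in all libraries. Such a gene is described as listed at the lowest value, and no fold is given against a group that was entirely at it. The deposited RPM columns sum to between 72.7% and 75.2% of the total that the unit implies, so the authors scaled by more than the reads of the listed genes. The smallest step between low values gives what 1 read was worth, 0.0787 to 0.114 RPM, and so 8770000 to 12710000 reads per library behind the scaling. With a tolerance of 0.1 read, between 87.0% and 88.9% of values under about 20 reads were whole numbers of reads. This was too few to recover a table of whole reads, so no test on counts was run. At 20 RPM a value rests on 175 to 254 reads, so levels well under 1 RPM carry large counting errors.

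Each column was matched to its library by the name that the labels give. Groups and replicate numbers (n1 and n2) came from the library titles. The 2 libraries of a group were not copies of one another: over genes with 20 RPM or more, the mean chi-square per gene between them was 32.1 in ESC, 59.0 in D2, 28.0 in D3 and 26.2 in D4, where sampling noise alone would give about 1. This reference covers counting error only and treats reads after PCR as independent, so a value above it shows only that the columns are not copies. The medians were lower, at 3.66, 11.49, 3.86 and 4.04, since genes far apart between the libraries weigh on the means. No columns of other samples were present.

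The main test was limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with 1 coefficient per group, all 8 libraries in the fit, eBayes with a trend, and no block, two-sided. All groups shared 1 estimate of the spread because 2 against 2 libraries leaves too few degrees of freedom, and the total degrees of freedom were 7.19. Genes with at least 1 RPM in at least 2 libraries were tested, 12930 in all. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 within the comparison and an absolute log2 fold change of at least 1. The comparisons were D2 against ESC, D3 against D2, D4 against D3 and D4 against ESC. Reported p-values are those of limma, adjusted over all tested genes of the comparison unless said otherwise. Gene lists were tested with camera of the same package at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over the 24 lists that had at least 3 tested members. There were 27 lists with 378 distinct genes, all found in the table, 1 of them under an older symbol. Calls were also counted after adjustment over each list alone. Overlaps of calls were counted beside the number that independent lists would share. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

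The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, at each step, the 7 called genes with the largest rise and the 7 with the largest fall among those whose 2 groups do not overlap and whose higher group has a mean of at least 20 RPM. It adds, from each list described, up to 4 called members with the largest absolute change, or up to 2 members of highest mean RPM where none was called. It also takes POU5F1, NANOG, SOX2, TBXT, CDX2, TBX6, PAX6 and the 39 HOX genes at every step, and the 5 largest changes in each direction for D4 against ESC. TRA2B, metallothionein genes other than MT1H, and genes named as shared between comparisons, were chosen after their values were seen, as were values of any gene in groups outside the comparison that named it. Some items that the rule takes are not reported here.

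The alternatives were pseudocounts of 0.1 and 5 RPM, no filter, a filter on a mean of 5 RPM, median-of-ratios rescaling and quantile normalization of the libraries, the replicate number as a block, a fit of only the 2 groups compared, eBayes without a trend, calls by adjusted p alone, an estimated correlation for lists, and leaving out each library in turn. Leaving out genes read at levels 8-fold or more apart within a group was added after seeing the data. When a library was left out, the lone library of its group was assumed to vary like the other groups.

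The test was tried on simulated values for the 12930 genes, drawn from a normal distribution with each gene's mean over all libraries and its fitted spread. A random set of genes with a mean log2 value above 3 was changed, so the rates below do not cover genes of low level. The values were normal and independent between genes, so they do not copy genes read at levels 8-fold or more apart within a group. The false calls given below may thus be too few. For D2 against ESC it recovered 65.7%, 91.0% and 92.4% of genes changed by 1.5, 2 and 3 on the log2 scale, with 9 false calls. For D3 against D2 it recovered 64.2% and 82.1% of those changed by 1.5 and 2 and all of those changed by 3, with 5 false calls, and for D4 against D3 82.1%, 77.6% and 90.9% with 3. A reference gene table of a newer human assembly was used only to find which genes lie within 5 kb of each other, and no coordinates were taken from it.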

Results

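Transcript levels were measured in 8 libraries of SA001, an established human embryonic stem cell line, in 4 groups of 2 libraries. The first group, ESC, was stem cells kept on Matrigel in mTeSR1 maintenance medium. The other groups, D2, D3 and D4, were floating embryoid bodies at days 2, 3 and 4 of differentiation towards axial progenitors, the cells that build the spinal cord and the trunk mesoderm of the embryo. Their N2B27 medium held CHIR-99021 at 3 µM, which activates WNT/beta-catenin signalling by inhibiting GSK3. It also held SB431542 at 20 µM, which blocks the NODAL/activin receptors, LDN at 0.1 µM, which blocks BMP receptors, and the ROCK inhibitor Y-27632 at 10 µM. The growth protocol states that SB431542 was taken out at day 3, whereas the treatment labels of both D3 and D4 list it, so which medium these libraries had is not settled. The title of the series names the pacing of HOX gene activation in these progenitors, so each day was compared with the stage before it, D4 was compared with ESC, and the 39 HOX genes were followed through all comparisons.

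Values were RPM, reads scaled to a common total per library, for 27103 genes, of which 12930 passed the low-value filter and were tested. The RPM of the listed genes summed to between 727460 and 752460 per library. The steps between low values imply 8770000 to 12710000 reads per library behind the scaling, so that 20 RPM corresponded to between 175 and 254 reads. Between 11707 and 11959 genes reached 1 RPM in each library. Across the tested genes, the log2 values of the 2 libraries of a group correlated at 0.957 in D2, 0.968 in D3, 0.971 in ESC and 0.974 in D4, where genes are not independent replicates. The first principal component held 60.4% of the variance and set ESC (-88.52 and -91.41) apart from D2 (15.87 and 1.22), D3 (39.31 and 29.91) and D4 (47.40 and 46.22). A small set of genes was read at levels far apart within a group. Of 6986 genes with 20 RPM or more in any library, 71 in ESC, 76 in D2, 76 in D3 and 68 in D4 differed 8-fold or more between the 2 libraries of the group. TRA2B, which encodes a splicing factor, had 618 RPM in one D2 library and 5.83 RPM in the other. All errors below are SD with n = 2, and fold changes are on the log2(RPM + 1) scale, which understates the change of genes with low levels. No label says that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

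Between ESC and D2 the cells lost transcripts of pluripotency regulators and gained transcripts of caudal and axial progenitor genes. CDX2, a caudal homeobox transcription factor, rose from 0.521 ± 0.0697 to 526 ± 27.3 RPM (limma, adjusted p = 1.86e-07), the largest rise among the called genes. PRDM14, a pluripotency transcription factor, fell from 187 ± 4.84 to 0.195 ± 0.136 RPM (limma, adjusted p = 3.54e-06). SOX2, which both stem cells and axial progenitors express, was at 220.8 ± 46.0 RPM in ESC and 226 ± 4.31 RPM in D2, a difference that did not pass the test (limma, adjusted p = 0.86). In all, 2012 of 12930 genes were called, 922 higher and 1090 lower in D2. For every list described as passing at this step, the count of called members was the same adjusted over the list alone.

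Of the 24 tested members of the pluripotency list, 17 were lower in D2 and none was higher. FOXD3 went from 64.3 ± 9.45 to 0.0985 ± 0.139 RPM, TDGF1, the NODAL co-receptor CRIPTO, from 31.6 ± 1.12 to 1.06 ± 0.789 RPM, and GDF3 from 16.7 ± 8.40 RPM to the lowest value the table lists. NANOG was also listed at that lowest value in both D2 libraries, against 6.92 ± 0.996 RPM in ESC. TDGF1P3, a copy of TDGF1 that can take its reads, was at 1127 ± 111 RPM in ESC and 55.4 ± 25.1 RPM in D2. The level of TDGF1 is therefore uncertain. POU5F1 was at 429 ± 260 RPM in ESC and 106 ± 65.7 RPM in D2 (limma, adjusted p = 0.0263). Its call was lost without the n1 library of ESC or the n2 library of D2, and reads can be shared with its near-identical copies. The list as a whole was lower by camera (adjusted p = 4.39e-10), with adjusted p = 0.102 with an estimated correlation.

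In the axial progenitor list 11 of 14 tested members were higher in D2 and none was lower. FGF17 rose from 0.267 ± 0.266 to 175 ± 45.8 RPM, the homeobox gene GBX2 from 1.00 ± 0.194 to 191 ± 59.4 RPM and CDX1 from 0.0570 ± 0.0805 to 65.9 ± 37.5 RPM. TBXT (brachyury, listed under its older symbol) rose from 0.346 ± 0.155 to 28.4 ± 18.1 RPM. The camera test gave adjusted p = 3.64e-11, and adjusted p = 0.0688 with an estimated correlation. The list of WNT/beta-catenin targets, which shares CDX1, CDX2, TBXT, NKD1 and SP5 with it, had 10 of 11 tested members higher (camera, adjusted p = 4.05e-11). It alone also passed with an estimated correlation (adjusted p = 0.0448). The WNT feedback inhibitors NKD1 and APCDD1 rose by 4.91 ± 0.16 and 5.42 ± 0.25 (SE) on the log2 scale, and outside the lists the WNT receptor FZD10 went from 0.862 ± 0.894 to 380.4 ± 38.2 RPM and WLS, which WNT secretion needs, from 0.923 ± 0.305 to 195 ± 21.7 RPM. FOXB1, a forkhead transcription factor, and PRTG, encoding the membrane protein protogenin, were also among the 7 largest rises, at 343 ± 50.5 and 208 ± 7.16 RPM in D2.

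Targets of NODAL/activin signalling were lower in D2 for 7 of 8 tested members (camera, adjusted p = 1.67e-07, and adjusted p = 0.102 with an estimated correlation). This list shares TDGF1 and GDF3 with the pluripotency list. SKIL fell from 281 ± 18.4 to 6.42 ± 2.07 RPM, and LEFTY1 from 31.3 ± 4.31 RPM to the lowest listed value. FOXH1, a cofactor of this pathway, was the member not called, at 108 ± 4.73 RPM in D2 (limma, adjusted p = 0.634). The epithelial list had 9 of 13 tested members lower (camera, adjusted p = 0.000817, and adjusted p = 0.346 with an estimated correlation), among them CLDN7, from 64.1 ± 3.36 to 2.41 ± 3.27 RPM, and KRT18, from 280.3 ± 11.3 to 44.1 ± 5.47 RPM. ZEB2, a repressor of epithelial genes, rose from 0.0966 ± 0.0246 to 88.9 ± 7.47 RPM. In the mesenchymal list 2 members were higher, ZEB2 and ZEB1, and 3 were lower, including the collagen genes COL1A1 (306 ± 31.9 to 52.0 ± 4.23 RPM) and COL1A2 (53.5 ± 10.2 to 11.3 ± 0.495 RPM), and the list did not pass (camera, adjusted p = 0.629).

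Neural progenitor genes were higher in D2 for 7 of 11 tested members (camera, adjusted p = 0.00137, and adjusted p = 0.102 with an estimated correlation). MSX1 rose from 0.0570 ± 0.0805 to 26.9 ± 4.46 RPM, PAX3 from 0.114 ± 0.161 to 9.74 ± 4.43 RPM and SOX21 from 7.66 ± 0.144 to 54.1 ± 33.4 RPM. PAX6 and TBX6, markers of neural and of paraxial mesoderm cells, stayed under the filter, with group means of at most 0.881 and 0.727 RPM in the 4 groups. HOX genes of paralog groups 1 to 4 and 5 to 9 were higher for 7 of 10 and 7 of 12 tested members (camera, adjusted p = 1.12e-06 and 0.000169), which became adjusted p = 0.109 and 0.157 with an estimated correlation. The FGF/ERK target list had 1 member higher and 3 lower of 15 and did not pass (camera, adjusted p = 0.16). Its member EGR1, and FOS, both immediate early genes of growth factor signalling, were among the largest falls, from 174 ± 84.7 to 0.537 ± 0.341 RPM and from 163 ± 0.182 to 1.37 ± 0.566 RPM. The cardiac actin gene ACTC1 (164 ± 24.6 to 0.345 ± 0.0731 RPM), the metallothionein gene MT1H (639.6 ± 14.4 to 5.91 ± 4.24 RPM) and HHLA1 (81.7 ± 10.9 RPM to the lowest listed value) were in the same group of falls. MT1H has close copies among the metallothionein genes, so its reads are uncertain.

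Of 3 tested forebrain and midbrain genes, HESX1 and OTX2 were lower (25.2 ± 2.49 to 0.197 ± 0.278 RPM, and 2.40 ± 0.167 to 0.0493 ± 0.0696 RPM) and LHX2 was higher, and the list did not pass (camera, adjusted p = 0.199). In the definitive endoderm list 1 of 4 tested members was higher and 2 were lower, and in the neural crest list 3 of 10 were higher and 3 lower, without a list call (camera, adjusted p = 0.246 and 0.708). The lateral mesoderm, endothelium and blood list had only 2 tested members, and both were lower, KDR from 156 ± 8.67 to 2.26 ± 1.27 RPM and TEK from 21.2 ± 0.220 to 7.10 ± 1.10 RPM. Among motor neuron and neuron genes, STMN2, a gene of growing neurites, rose from 1.16 ± 0.0286 to 91.4 ± 15.2 RPM, and the other 4 tested members were not called (camera, adjusted p = 0.697). In the retinoic acid list CRABP2, which encodes a carrier of retinoic acid inside cells, rose from 152 ± 15.7 to 1620.0 ± 201 RPM, and the list did not pass (camera, adjusted p = 0.288). Of 85 called genes chosen by the naming rule, 14 lost the call when 1 library was left out, among them POU5F1, SOX21, TEK, MKI67 and HOXD1. The call count was 1053 with a pseudocount of 5 RPM, 1269 with a filter on a mean of 5 RPM and 3470 by adjusted p alone.

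Marker genes from each of these groups are plotted per library.

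**Figure D1:**
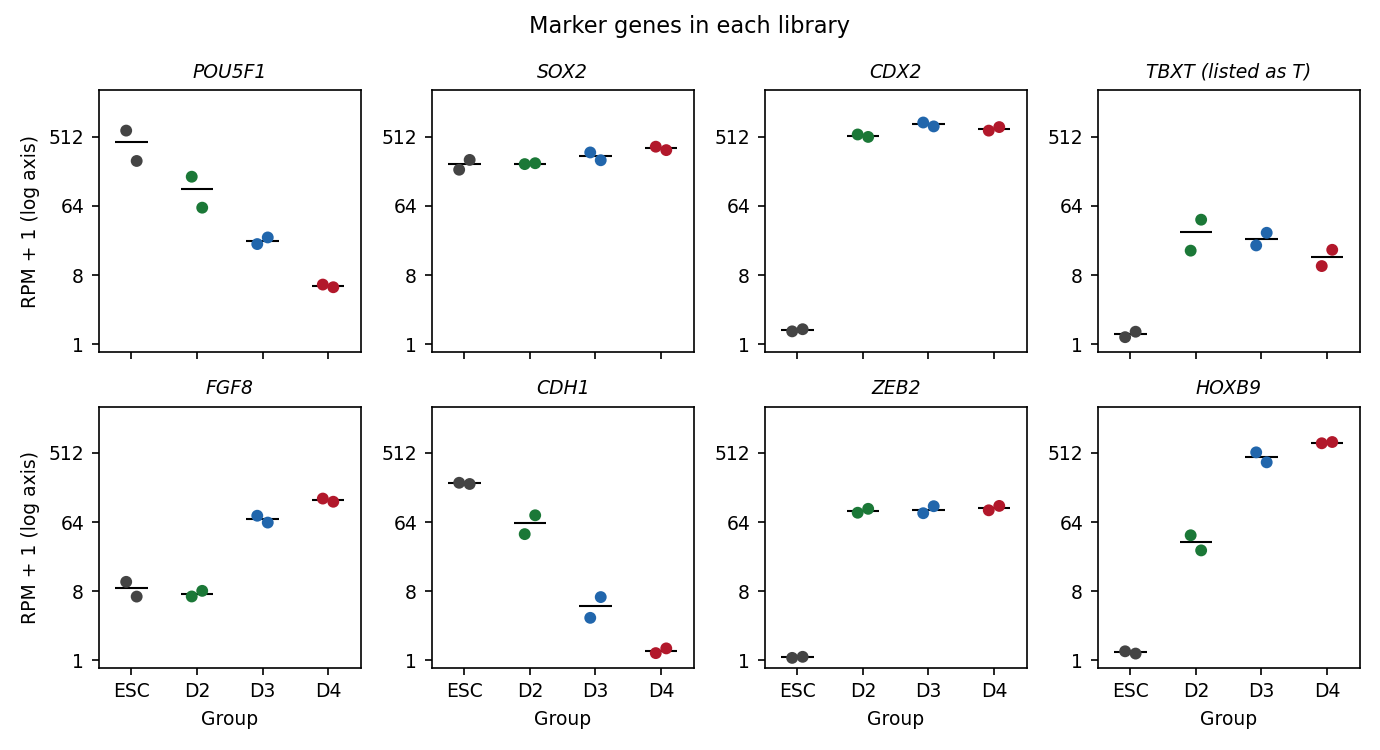
Levels of 8 marker genes in each library, as RPM + 1 on a log axis against the group (ESC, D2, D3, D4). Points are single libraries and short lines are the mean of the 2 libraries of a group. The group mean of POU5F1 goes from 429 RPM in ESC to 4.77 RPM in D4, that of SOX2 from 220.8 to 359 RPM, and that of CDX2 from 0.521 to 526 RPM between ESC and D2.

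Between D2 and D3 the genes called higher included HOX genes of paralog groups 5 to 9 and FGF8. Those called lower included 2 members of the epithelial list and 2 of the pluripotency list. HOXB9 rose from 34.1 ± 11.1 to 451 ± 95.1 RPM (limma, adjusted p = 0.00107), and FGF8, a growth factor of the caudal embryo, from 6.46 ± 0.889 to 69.1 ± 10.2 RPM (limma, adjusted p = 0.00159). CDH1, encoding E-cadherin, fell from 60.4 ± 24.0 to 4.15 ± 2.20 RPM (limma, adjusted p = 0.00558). CDX2 was at 738 ± 61.1 RPM in D3 and TBXT at 23.0 ± 6.36 RPM, neither of them past the test against D2. In all, 167 genes were called, 78 higher and 89 lower in D3.

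Of 12 tested HOX genes of paralog groups 5 to 9, 9 were higher in D3, also adjusted over the list alone (camera, adjusted p = 1.65e-17, and adjusted p = 0.0821 with an estimated correlation), and of groups 1 to 4 it was 1 of 10, HOXD4, and 2 adjusted over the list alone (camera, adjusted p = 0.000917, and adjusted p = 0.338 with an estimated correlation). In the FGF/ERK target list 3 of 15 were higher over all genes and 5 adjusted over the list alone (camera, adjusted p = 0.000276, and adjusted p = 0.146 with an estimated correlation). These were IL17RD (50.9 ± 4.89 to 218 ± 8.03 RPM), DUSP6 (60.2 ± 11.8 to 172 ± 2.23 RPM) and ETV5 (38.4 ± 0.771 to 87.2 ± 13.1 RPM), of which IL17RD and DUSP6 encode feedback inhibitors of the pathway. The epithelial list had 2 of 13 members lower, CDH1 and the splicing regulator ESRP2 (3.97 ± 1.08 to 0.740 ± 0.0898 RPM), and 4 adjusted over the list alone (camera, adjusted p = 4.07e-07, and adjusted p = 0.338 with an estimated correlation). The mesenchymal gene VIM rose from 142 ± 63.6 to 554 ± 148 RPM, while its list did not pass (camera, adjusted p = 0.116). In the pluripotency list DNMT3B (33.7 ± 0.0789 to 10.5 ± 3.68 RPM) and VRTN (153 ± 35.0 to 63.2 ± 6.63 RPM) were lower, and 5 were lower adjusted over the list alone (camera, adjusted p = 2.35e-05, and adjusted p = 0.338 with an estimated correlation). POU5F1 was at 21.5 ± 3.16 RPM in D3 and SOX2 at 284 ± 47.1 RPM, and neither passed against D2 (limma, adjusted p = 0.127 and 0.497). The POU5F1 copies POU5F1B, POU5F1P3 and POU5F1P4, which can take its reads, were called lower in D3. POU5F1B, for example, went from 573 ± 145 to 177 ± 29.3 RPM. Of the NODAL/activin targets only FOXH1 was lower, from 108 ± 4.73 to 43.9 ± 8.20 RPM, and MIXL1, a gene of the primitive streak, fell from 12.6 ± 0.403 to 2.91 ± 1.22 RPM. WNT/beta-catenin targets and neural progenitor genes had no called member (camera, adjusted p = 0.804 and 0.625). The paraxial mesoderm list, of whose 18 members only 4 were tested, and the hypoxia and glycolysis list passed in the higher direction (camera, adjusted p = 0.0403 each). Neither had a member called over all genes. Adjusted over the list alone, the former had 0 members called and the latter 2 higher and 1 lower. With an estimated correlation the camera adjusted p became 0.379 and 0.615.

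Over all genes, TMEM132C rose most among those taken by the naming rule, from 5.03 ± 1.27 to 183 ± 26.1 RPM, with HOXC6 (1.66 ± 0.123 to 27.9 ± 0.280 RPM), HOXB6 (2.17 ± 0.430 to 26.3 ± 0.080 RPM), the noncoding LOC400043 and KCTD2 also among the 7 largest rises. The largest falls included TDGF1P3, a copy of TDGF1 that can take its reads, from 55.4 ± 25.1 to 1.84 ± 1.49 RPM, OAF, SDF4, FAM111B, CDH1 and ESRG, a noncoding RNA of stem cells, from 352 ± 96.2 to 27.1 ± 13.2 RPM. Some of these changes ran against a flat or alternating course. SDF4 was at 125 ± 12.3 RPM in ESC, 117 ± 21.3 in D2, 6.94 ± 1.88 in D3 and 107 ± 9.0 in D4. KCTD2 was at 26.1 ± 7.58, 1.71 ± 0.776, 33.9 ± 0.101 and 1.82 ± 0.259 RPM in the same order. With a non-overlapping change of 8-fold or more and 20 RPM or more in the higher group, D3 and D2 differed in 28 genes, and the 2 ways of mixing a D2 with a D3 library in each group gave 19 and 7. Chance alone keeps 2 against 2 libraries from overlapping in 33.3% of genes. The call count fell without the n1 library of D3 and rose without the n1 library of D2. It also fell without either library of ESC or of D4, which enter this comparison only through the shared spread. With only D2 and D3 in the fit 28 genes were called, with no filter on low values 45, and 15 of 33 called genes chosen by the naming rule lost the call when 1 library was left out, among them DNMT3B, VRTN, DUSP6, ETV5, ESRP2, VIM, FOXH1, MIXL1 and 4 HOX genes (HOXB7, HOXC9, HOXD4 and HOXD9).

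Between D3 and D4, 70 genes were called, 34 higher and 36 lower in D4, among them 2 HOX genes that were higher and 2 pluripotency genes that were lower. HOXC8 rose from 16.4 ± 1.10 to 62.8 ± 9.47 RPM (limma, adjusted p = 0.0137), and DNMT3B, a de novo DNA methyltransferase of stem cells, fell from 10.5 ± 3.68 to 0.215 ± 0.189 RPM (limma, adjusted p = 0.00242). CNTFR, the receptor of ciliary neurotrophic factor, rose from 7.03 ± 1.54 to 133 ± 16.4 RPM (limma, adjusted p = 0.00127), and NCAN, a proteoglycan of nervous tissue, from 0.668 ± 0.306 to 23.9 ± 3.10 RPM (limma, adjusted p = 0.00127). The HOX calls were lost without any 1 library of D3 or D4, and CNTFR and NCAN are among the 20 genes of 8-fold change, where mixed groupings of these libraries gave 16 and 10.

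Of the HOX genes of paralog groups 5 to 9, 2 of 12 were higher over all genes and 4 adjusted over the list alone (camera, adjusted p = 6.39e-05, and adjusted p = 0.398 with an estimated correlation). In the pluripotency list 2 of 24 were lower, DNMT3B and ZFP42 (7.76 ± 2.64 to 1.39 ± 0.417 RPM), and 4 adjusted over the list alone (camera, adjusted p = 6.39e-05, and adjusted p = 0.398 with an estimated correlation). The epithelial list had no member called over all genes and 4 lower adjusted over the list alone (camera, adjusted p = 6.39e-05, and adjusted p = 0.528 with an estimated correlation), with EPCAM at 38.8 ± 14.9 RPM in D3 and 12.1 ± 1.13 RPM in D4. The list of p53 targets and apoptosis genes, at a median log2 change of -0.39, and the WNT/beta-catenin targets, at -0.42, passed in the lower direction with no member called over all genes, and with 0 and 1 lower adjusted over the list alone (camera, adjusted p = 0.000444 and 0.0206). With an estimated correlation these became adjusted p = 0.528 and 0.398. BAX was at 188 ± 33.8 RPM in D3 and 135 ± 11.6 RPM in D4, and CDX2 at 738 ± 61.1 and 647 ± 48.8 RPM. Of the axial progenitor genes WNT8A was lower (16.2 ± 0.712 to 4.51 ± 0.384 RPM), and FGF8 was at 123 ± 8.35 RPM in D4 without passing the test against D3. In the NODAL/activin list, the pathway of the inhibitor that the protocol, unlike the labels, takes out at day 3, FOXH1 was lower (43.9 ± 8.20 to 12.3 ± 0.684 RPM), the other 7 tested members were not called, and the list did not pass (camera, adjusted p = 0.871). In the definitive endoderm list the chemokine receptor gene CXCR4 rose from 6.69 ± 2.19 to 27.6 ± 0.0958 RPM and FOXA3 fell from 8.62 ± 1.05 to 2.15 ± 0.084 RPM, and the list did not pass (camera, adjusted p = 0.766). POU5F1, SOX2 and TBXT were at 4.77 ± 0.326, 359 ± 26.1 and 12.8 ± 4.66 RPM in D4, not past the test against D3 (limma, adjusted p = 0.265, 0.609 and 0.658). The copies POU5F1B, POU5F1P3 and POU5F1P4 were called lower again, with POU5F1B at 43.1 ± 11.3 RPM in D4.

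Some of the other large changes at this step were in genes with a steady level in the groups before. CERS6, a ceramide synthase gene, was at 5.16 ± 0.202, 4.12 ± 0.593 and 4.28 ± 0.313 RPM in ESC, D2 and D3 and at 99.3 ± 7.79 RPM in D4. CROCC went from 1.81 ± 0.164 to 33.0 ± 0.470 RPM, SERINC2 from 43.6 ± 3.21 to 2.13 ± 1.05 RPM and CD2BP2 from 59.6 ± 0.315 to 6.44 ± 2.19 RPM. SDF4 and WNK2 (1.53 ± 0.231 to 24.0 ± 0.137 RPM) rose and KCTD2 fell, each of them after the opposite change from D2 to D3. The remaining falls among the 7 largest were ESRG, the serotonin receptor gene HTR1D (105 ± 23.9 to 19.1 ± 1.54 RPM), GABARAPL3 and POU5F1P3, of which the last 2 are near-identical copies of GABARAPL1 and POU5F1 and so uncertain. GABARAPL1 itself was called higher in D4 than in D3, opposite to GABARAPL3. By the 8-fold measure D4 and D3 differed in 20 genes, CERS6, CROCC, SERINC2, CD2BP2, CNTFR and NCAN among them, and the 2 mixed groupings of the same 4 libraries gave 16 and 10. Among genes called at both later steps, which share the D3 libraries, 20 went on in the same direction, 12 were lower and then higher, and 4 were higher and then lower. The call count fell without either library of D4, and without either library of ESC, which enter this comparison only through the shared spread. It was 41 with only D3 and D4 in the fit and 22 with no filter. Of 23 called genes chosen by the naming rule, 11 lost the call when 1 library was left out, among them ZFP42, ESRG, WNK2, WNT8A, CXCR4, FOXA3, HOXA6, HOXC8, GABARAPL3 and POU5F1P3.

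**Figure D2:**
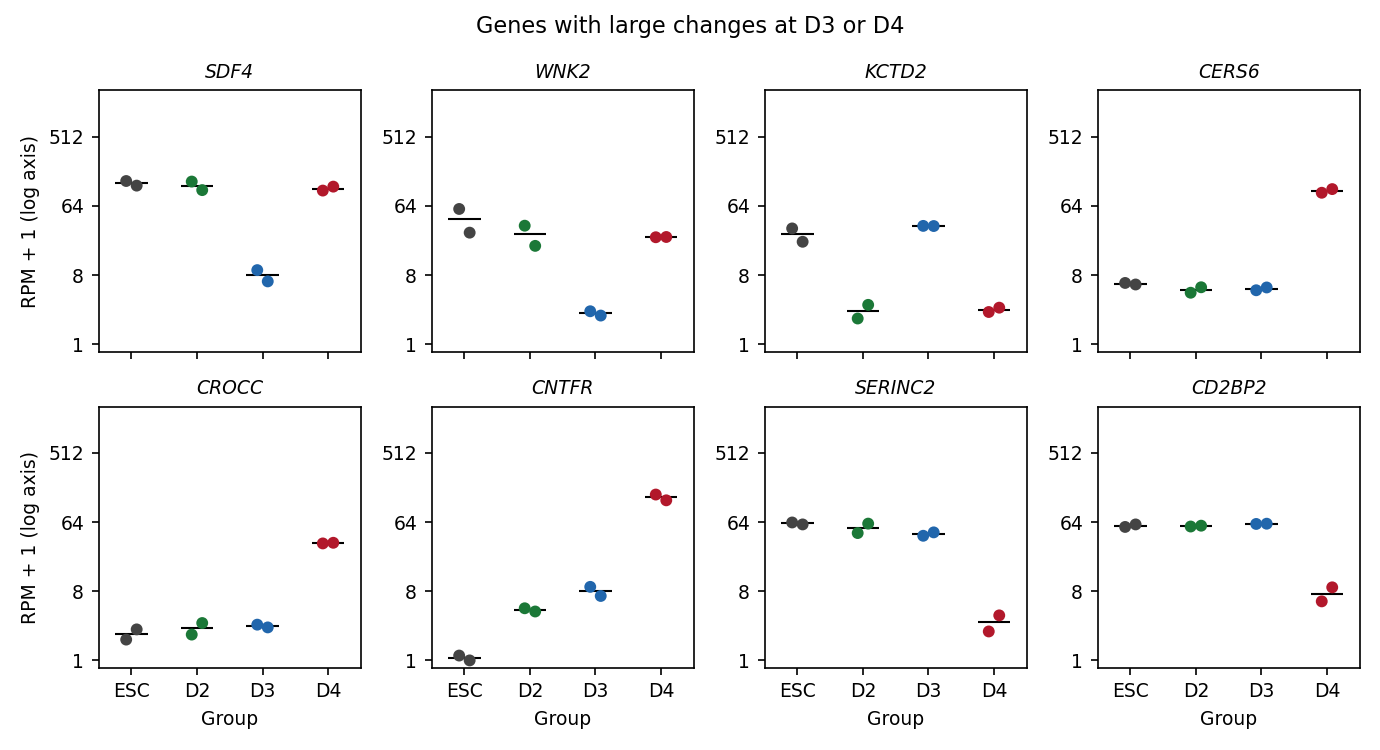
Levels of 8 genes among the largest changes at D3 or D4 in each library, as RPM + 1 on a log axis against the group. Points are single libraries and short lines are the mean of the 2 libraries of a group. SDF4 is at 125, 117, 6.94 and 107 RPM in ESC, D2, D3 and D4, and CERS6 is at 5.16, 4.12, 4.28 and 99.3 RPM.

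Over the whole course, from ESC to D4, the cells went from a pluripotency profile to one of caudal genes and HOX genes of paralog groups 1 to 9. HOXB9 (0.271 ± 0.0614 to 694 ± 18.5 RPM), CDX2 (0.521 ± 0.0697 to 647 ± 48.8 RPM), FOXB1, FGF17 and FZD10 were the 5 largest rises. TDGF1P3 (1127 ± 111 to 0.253 ± 0.0115 RPM), MT1H, ESRG (1138 ± 32.8 to 2.76 ± 0.656 RPM), DNMT3B (296 ± 20.8 to 0.215 ± 0.189 RPM) and ARHGEF5 were the 5 largest falls. In all, 3034 genes were called, 1400 higher and 1634 lower in D4. The pluripotency list had 21 of 24 members lower, the NODAL/activin list 8 of 8 and the epithelial list 11 of 13, with CDH1 at 203 ± 5.26 RPM in ESC and 0.340 ± 0.134 RPM in D4. Higher were 13 of 14 axial progenitor genes, 9 of 11 WNT/beta-catenin targets, 8 of 11 neural progenitor genes and 22 of 22 tested HOX genes. Adjusted over the list alone the counts were the same, with 1 more neural progenitor gene lower. These lists passed camera with adjusted p between 8.9e-12 and 0.000709, and none passed with an estimated correlation, where the adjusted p was 0.192 for the epithelial list and between 0.0665 and 0.0683 for the others. The p53 list passed as well, with PHLDA3 and MDM2 lower among 15 members (camera, adjusted p = 0.0327, and adjusted p = 0.678 with an estimated correlation). The proliferation list did not pass (camera, adjusted p = 0.713), with TYMS (161 ± 3.29 to 495 ± 69.1 RPM) and MKI67 (42.7 ± 10.3 to 98.3 ± 11 RPM) higher and MCM5 (351 ± 50.4 to 132 ± 19.5 RPM) lower. The call count was 1720 with a pseudocount of 5 RPM, 1944 with a filter on a mean of 5 RPM and 5149 by adjusted p alone. Of 95 called genes chosen by the naming rule, 10 lost the call when 1 library was left out, among them MDM2 and MKI67.

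HOX genes of low and of high paralog number were both higher by D2, and at D3 those called were 9 of 12 of paralog groups 5 to 9 and 1 of 10 of groups 1 to 4. In ESC no HOX gene had a group mean above 0.271 RPM. At D2, 14 of 22 tested genes were higher than in ESC, among them HOXB1 at 42.5 ± 23.9 RPM, HOXB9 at 34.1 ± 11.1 RPM and HOXB4 at 27.2 ± 7.76 RPM. At D3, 10 were higher than at D2, namely HOXA7, HOXB5, HOXB6, HOXB7, HOXB9, HOXC6, HOXC8, HOXC9, HOXD4 and HOXD9. HOXC8 had been at the lowest listed value in both D2 libraries and reached 16.4 ± 1.10 RPM, and HOXB5 and HOXB7 went from 3.56 ± 0.515 to 21.2 ± 4.84 RPM and from 11.2 ± 3.58 to 39.7 ± 7.03 RPM. At D4, 2 were higher than at D3, HOXC8 and HOXA6, the latter at 8.98 ± 2.45 RPM against 1.17 ± 0.510 RPM. Adjusted over the HOX list alone, 14, 11 and 4 genes were higher at the 3 steps and 1 was lower at the last. The 17 HOX genes under the filter had at most 0.523 RPM in any library, and none of the 12 genes of paralog groups 10 to 13 exceeded 0.402 RPM. At this depth, that leaves levels of a few reads that could not be tested. Both rescalings of the libraries gave the same counts of 14, 10, 2 and 22, and with a pseudocount of 5 RPM the D2 count was 8. The count at D3 was 6 without the n1 or n2 library of ESC or the n2 library of D2, 5 with no filter and 4 with only D2 and D3 in the fit. The D4 count was 0 without the n2 library of ESC or without any 1 library of D3 or D4, and 1 without the n1 library of ESC. The libraries of ESC enter the D3 and D4 counts only through the shared spread. HOX genes overlap antisense RNAs and no source used here says whether strand was counted, so reads of a HOX gene and of its antisense partner cannot be told apart.

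**Figure D3:**
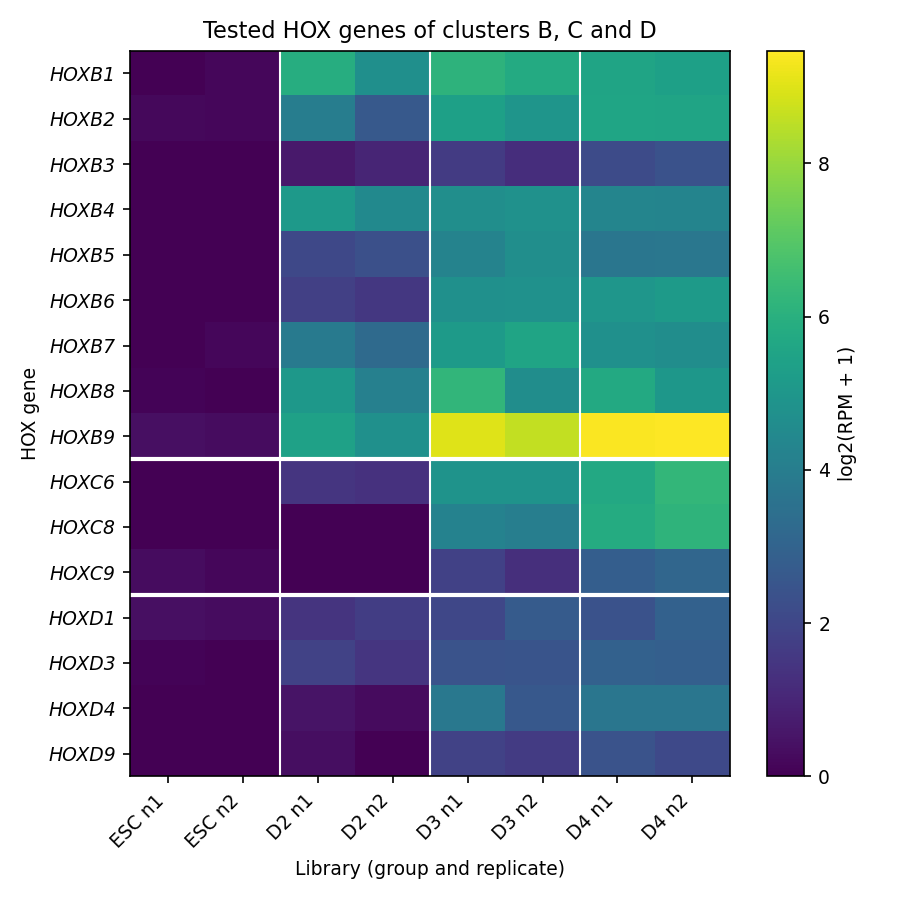
Levels of the tested HOX genes of clusters B, C and D in the 8 libraries, as log2(RPM + 1) by colour, with genes in rows ordered by cluster and paralog number and libraries in columns. HOXB1 reaches 42.5 RPM at D2, and HOXB9 goes from 34.1 RPM at D2 to 451 RPM at D3 and 694 RPM at D4.

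Genes called at the first step were compared with those called at the third. The 2 comparisons share no library, but they come from 1 fit with a spread per gene shared over all libraries, so genes of low spread tend to be called in both and independent lists are not the proper reference. Of the 36 genes lower in D4 than in D3, 15 had also been lower in D2 than in ESC, where independent lists would share 3.03. They include DNMT3B, ZFP42, ESRG, ZSCAN10, FOXA3 and the POU5F1 copies POU5F1B, POU5F1P3 and POU5F1P4, whose reads are not independent of each other. Of the 34 genes higher in D4, 7 had also been higher at the first step, CNTFR among them, where independent lists would share 2.42. In opposite directions, 6 genes were higher and then lower (2.57 for independent lists) and 6 were lower and then higher (2.87), an excess near that of the genes higher at both steps.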

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

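Leaving out the genes read at 2 far-apart levels within a group was chosen only after the data were seen, and the other settings were planned. The call counts of the 4 comparisons fell outside 1.5 times the reported ones as follows. With a pseudocount of 5 RPM, 1053 genes were called for D2 against ESC and 1720 for D4 against ESC, and with a filter on a mean of 5 RPM 1269 and 1944. By adjusted p alone these were 3470 and 5149. With no filter on low values 45 genes were called for D3 against D2 and 22 for D4 against D3, and with only the 2 compared groups in the fit 28 and 41. Calls by adjusted p alone drop the fold threshold, which can only add genes, and both filters change how many genes are tested. A pseudocount of 5 RPM makes log2 changes smaller, most of all at low levels. A fit of only 2 groups leaves fewer degrees of freedom for the spread. How much of each shift these account for was not tested. HOX calls were 8 for D2 against ESC with a pseudocount of 5 RPM. For D3 against D2 they were 5 with no filter and 4 with only 2 groups, and for D4 against ESC 13 with the mean filter, where 13 were tested. For D4 against D3 they were 0 with a pseudocount of 0.1 RPM and 1 with no filter, with the mean filter, with the replicate number as a block and with only 2 groups. The lists called for D3 against D2 were 4 with the mean filter, and with an estimated correlation the lists called in the 4 comparisons were 1, 0, 0 and 0. Leaving out 1 library at a time, with the lone library of a group assumed to vary like the other groups, gave 1607 to 2210, 67 to 270, 40 to 79 and 2629 to 3085 genes. It gave 13 to 14, 6 to 10, 0 to 2 and 22 HOX genes, and 8 to 11, 4 to 10, 4 to 6 and 8 to 10 lists. The replicate block gave 2085, 190, 72 and 3092 genes, and the deviations of n1 and n2 from their group means correlated at 0.038 to 0.242 between groups across genes. Without the genes of far-apart levels the counts were 2063, 204, 79 and 3056. The overlap of the genes lower at D2 and lower at D4 was 14 with median-of-ratios rescaling and 19 by adjusted p alone. Named genes gave 5516 values on the same side of the threshold, 380 that lost the call, 9 that gained it and 0 of opposite direction over these settings. The planned tests with edgeR and DESeq2 were not run, since whole reads were not recovered from the RPM values. At 8770000 to 12710000 reads per library, levels of a few reads limit the HOX genes of groups 10 to 13.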

Other observations

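The metallothionein genes were chosen after their values were seen, as were the genes of other lists named here. Metallothioneins, which bind zinc and copper, were lower in D2 than in ESC for 7 of 8 tested genes, taken as MT2A and those named MT1 with a single letter. Outside this set, MT1HL1 was at 174.5 and 308 RPM in the ESC libraries and at 6.44 and 65.6 RPM in the D2 libraries. MT1G went from 65.6 ± 3.35 to 0.665 ± 0.177 RPM (limma, adjusted p = 3.91e-05), MT1X from 208 ± 12.9 to 21.7 ± 4.44 RPM (limma, adjusted p = 0.000201), MT2A from 365 ± 126 to 62.7 ± 0.762 RPM (limma, adjusted p = 0.00277) and MT1E from 109 ± 6.76 to 6.35 ± 3.96 RPM (limma, adjusted p = 0.00237), with n = 2. MT1A, at 1.26 ± 0.240 RPM in ESC, was not called (limma, adjusted p = 0.0931). These genes are near-identical copies that can share reads, so the values of single members are uncertain. At the same step the BMP/SMAD1 target list had 3 members higher and 3 lower of 10 (camera, adjusted p = 0.922), the hypoxia and glycolysis list 2 higher and 4 lower of 16 (0.246), the cholesterol synthesis list 1 lower of 17 (0.37), the NOTCH list 3 lower of 9 (0.0527) and the list of unfolded protein and heat stress genes 1 lower of 12 (0.0554).

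Of the tests below, those of neighbouring genes, of mirrored genes, of the HOX order, of the move from Matrigel and of FGF/ERK targets were chosen only after the result was seen. The patterns themselves, and the measure of 8-fold at 20 RPM, came from looking at these values, so what follows are hypotheses.

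The first pattern is that 201 genes were read at levels 8-fold or more apart in the 2 libraries of some group. Among the 71 genes so read in ESC, 25.8% of the pairs of libraries within D2, D3 and D4 and 24.3% of those between these groups were 8-fold apart, a ratio of 1.06 (bootstrap 95% interval 0.88 to 1.25 over 1000 draws of genes). At D2, D3 and D4 these genes thus differed about as often within a stage as between stages. They were chosen for a difference within the ESC stage, which leaves out genes that the stage sets, so the ratio says nothing about other genes. Of 277 cases with a position in the reference, 2.5% (exact 95% interval 1.02 to 5.14) had a gene within 5 kb that gained a like amount, which was thus rare. Of 35 genes that switched by 100 RPM or more, 5.7% (0.7 to 19.16) were mirrored by another gene, and 17.1% had a gene that moved alike. Mirroring would miss reads split over several genes, or moved to a gene with a change of its own. Other moves of reads between listed genes therefore stay open. For D2 against ESC 185 genes met the 8-fold measure with the real groups and 12 on average with the 2 mixed groupings (highest 16), for D3 against D2 28 and 13 (highest 19), and for D4 against D3 20 and 13 (highest 16), where 3 groupings are too few for a share under 0.05. The highest mixed count came each time from setting the n1 libraries against the n2 libraries, so the mixed counts are not free of the replicate number. Switching of single libraries therefore may account for part of the largest changes at D4 (CERS6, SDF4, CROCC, SERINC2, and as much CNTFR and NCAN) and stays open at D3, whereas at D2 it would give too few, and what makes a library switch, for example an amplicon that failed, was not tested.

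The second pattern is the order of the HOX genes. Across the 22 tested HOX genes, the D2 level as a share of the D4 level fell with the paralog number (Spearman rho -0.57, permutation p = 0.0136 within clusters, adjusted p = 0.0407 over 3 relations, and Pearson r -0.51, permutation p = 0.00952), where genes are not independent replicates. A candidate explanation is later activation of higher paralog numbers, as a collinear order would give. Over the 13 genes with 10 RPM or more at D4 rho was -0.49 (permutation p = 0.114, adjusted p = 0.171), so the relation no longer passed. An appearance of lateness from low levels would tie the share to the D4 level, and that rho was -0.11 (permutation p = 0.498, bootstrap SD 0.23 over genes). The D4 level is also the denominator of the share, which pulls this rho down, so it cannot decide on low levels as the cause. Single genes went both ways. HOXB9 had a share of 4.9% at 694 RPM and HOXA5 77.4% at 3.85 RPM, whereas HOXC9 had 0.0% at 6.89 RPM and HOXD9 3.5% at 3.79 RPM.

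The third pattern is the fall of actin and growth-response genes such as ACTC1, FOS and EGR1 at D2. In a list of actin cytoskeleton genes and targets of SRF and YAP, written after this fall was seen and without these 3 genes, the median log2 change over 20 tested members was -1.17 at D2 (quartiles -2.78 and -0.53, 11 called lower and 0 higher), -0.07 at D3 and -0.16 at D4. This may follow from the move from Matrigel to floating bodies, but medium, ROCK inhibitor and stage changed at the same step, so these cannot be told apart. Lower FGF/ERK signalling is another candidate explanation, with a median of -0.81 in its list at D2, which did not pass (camera, adjusted p = 0.16), and it stays open.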
